A study of Homo sapiens with 2 samples.

How the data were processed

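The series holds 2 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from C4-2B cells, a subline of the LNCaP human prostate cancer line that forms bone metastases in mice. In 1 library, DNA bound by Flag-tagged Runx2 was recovered with an antibody against the Flag epitope, a short peptide added to a protein so that it can be pulled down. The other library is input DNA, which was sequenced without immunoprecipitation and serves as background. Groups were taken from the antibody entry of the labels, which gives 1 Runx2 library and 1 input library. There were no replicates, so no spread between cultures could be estimated.

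The values come from a peak list that the authors deposited for the Runx2 library. Library preparation followed the sequencer maker's protocol, per the labels' protocols. The peaks are on human genome build hg18, per the submitters' processing notes. The aligner, the peak caller, its threshold and the way in which the input library entered peak calling are not given in the sources used here. The list has the 6 columns of a BED file: chromosome, start, end, name, score and strand. The score in the deposited list is 0 for each of the 1603 peaks, the strand is plus for each, and each peak is 500 bases wide. The number in a peak's name rises by 1 from peak to peak along each chromosome, so it records position and not strength. Peaks could therefore not be ranked, and no peak height, enrichment or p-value was used. Fixed-width regions also do not show how broad the signal was. Read counts and sequencing depth are unknown, and no file of the input library was used here.

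Several comparisons fixed before the data were examined could not be run. The stricter thresholds and the relation of score to width need scores or widths that vary. The location of peaks relative to genes, 9 gene lists near peaks and the RUNX sequence motif need a genome or annotation of build hg18. The gene table at hand is from assembly GRCh38.p14, so its coordinates were not set against the peaks. It gave only the number of protein-coding genes per chromosome, 19974 over the autosomes and X. For the same reason no gene is named for any peak. The rule for named regions, also fixed in advance, asked for the 10 highest-ranked peaks, the 5 widest peaks and the 5 largest groups of peaks chained within 10 kb, with ties broken by score. Without scores and widths that vary, it yielded only the 3 groups of 3 peaks, since all other groups were tied at 2 peaks. Other named regions were chosen after their values were seen.

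The span of a chromosome was the distance from its first to its last peak, because chromosome lengths of build hg18 were not used here. Spans include unassembled sequence such as centromeres. The number of peaks on each of the 22 autosomes and X was compared with the number expected from its share of the summed span. The chi-square statistic was tested against 100000 multinomial draws, whose smallest possible p is 1e-05. Each chromosome was tested with a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 23 chromosomes, at a threshold of 0.05. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only. The binomial test treats peaks as independent. A second test, added after the data were seen, therefore took 304 windows of 10 Mb as the units and permuted their peak counts over the chromosomes 100000 times. The single peak on Y was left out of these tests.

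Spacing was measured as the gap between the facing edges of neighbouring peaks, and a pair within 10 kb was called close. The number of close pairs was compared with 1000 random placements that kept each chromosome's number of peaks, their width and the span; the test is one-sided and its smallest possible p is 0.001. For the starts of chromosomes, placements ran from position 1 to the last peak. Random peaks were allowed to overlap, which the deposited peaks do not do. Alternatives were other distances, merging of near peaks (checked with bedtools 2.31.1), placement within 1 Mb bins or 10 Mb windows, other definitions of the span, expectation from gene number, and leaving out chromosomes. The same peaks were also counted as chained groups. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

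The tests were tried on simulated data, with fewer permutations and placements than on the deposited list. For the permutation and placement tests, the rates below are therefore approximate. Among 200 simulated sets of 1602 independent, evenly spread peaks, X was called in 0.5%. Other chromosomes were called 0.03 times per set on average. With X raised 1.5 times it was called in 88% of 200 sets, and with X raised 2 times in 100%. The deposited peaks lay in groups, so these rates do not carry over to the exact binomial test on the list. With windows as units, X raised 2 times was called in 66% of 50 sets and unchanged X in 0%. In the sets with X unchanged, other chromosomes were called 0.1 times per set on average. The spacing test called 100% of 20 sets with 40 added close pairs and 0% of 20 sets with none.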

Results

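Runx2 is a Runt-domain transcription factor, best known as a regulator of osteoblast differentiation, and the series asked where it binds the genome of prostate cancer cells. Binding was mapped by ChIP-seq of Flag-tagged Runx2 in C4-2B cells. There was 1 Runx2 library and 1 input library, without replicates. The peak list of the Runx2 library held 1603 regions of 500 bases, which together covered 801.5 kb. Peaks were found on 24 chromosomes, the 22 autosomes, X and Y, and 0 peaks lay on mitochondrial or unplaced sequence. Y carried 1 peak, at positions 10593880 to 10594379 of build hg18. The list gave positions alone, with no height or enrichment, so the peaks were compared by where they lay. Sequencing depth was unknown. Each p-value below describes the arrangement of peaks in this 1 list and not the spread between cultures.

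The first comparison asked whether Runx2 peaks were spread over the chromosomes in proportion to their span. They were not. Chromosomes X and 4 carried the highest density of peaks by this span, with 159 peaks on X (1.06 per Mb) and 185 on chromosome 4 (0.973 per Mb). The density over all 23 chromosomes tested was 0.562 peaks per Mb. The ranking depends on the span: without the longest peak-free stretch of each chromosome, chromosomes 21 (2.97 times its expected number) and 19 (1.87) lay above X (1.72) and 4 (1.58). Those stretches were found from the same peaks, so this ranking is partly set by the cut. The cut took chromosome 21 from 35.7 to 11.3 Mb and chromosome 19 from 61.7 to 42.3 Mb. It took X from 150 to 141 Mb and chromosome 4 from 190 to 178 Mb. Relative to gene number, chromosome 4 and then chromosome 13, at 2.77, lay above X at 2.34. X and chromosome 4 together held 21.5% of the peaks on 11.9% of the span. X had 1.89 times its expected number of peaks (95% exact interval 1.62 to 2.18, adjusted p = 1.26e-12, exact binomial test). Chromosome 4 had 1.73 times its expected number (95% exact interval 1.50 to 1.98, adjusted p = 8.65e-12, exact binomial test). Set against the pooled autosomes, at 0.534 peaks per Mb, the density on X was 1.98 times theirs (95% exact interval 1.67 to 2.34). Chromosome 4 set against the other autosomes, at 0.501 peaks per Mb, gave a ratio of 1.94 (95% exact interval 1.66 to 2.27).

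Among the other chromosomes, 19, 13 and 2 also exceeded their expected number in the binomial test, and the call of each depended on the setting. Chromosome 19, which is rich in genes, had 52 peaks and a ratio of 1.50 (95% exact interval 1.12 to 1.96). Relative to its number of protein-coding genes the direction turned, with a ratio of 0.447, and with peaks chained within 100 kb counted once it lost its call (ratio 1.40, adjusted p = 0.0913, exact binomial test). Chromosome 13 had 75 peaks and a ratio of 1.40 (95% exact interval 1.10 to 1.74), and chromosome 2 had 162 peaks and a ratio of 1.19 (95% exact interval 1.02 to 1.38). Chromosome 13 lost its call with the span counted from position 1 (adjusted p = 0.120, exact binomial test). That span adds the unassembled p arms of chromosomes 13, 14, 15, 21 and 22, which lowers their ratios by construction. Chromosome 2 lost its call without chromosome 5 (adjusted p = 0.107, exact binomial test). The same held without the longest peak-free stretches (ratio 1.05, adjusted p = 0.601, exact binomial test). Of the chromosomes below their expected number, 7 passed the threshold. By this span chromosome 5 had the lowest ratio, 0.490, with 49 peaks against 99.9 expected (adjusted p = 8.34e-08, exact binomial test). Chromosomes 14 and 10 followed at 0.504 and 0.505, with 23 and 38 peaks; with the span counted from position 1, chromosome 14 (0.420) lay below chromosome 5 (0.513). Chromosome 9 had a ratio of 0.588, chromosome 17 of 0.625, chromosome 3 of 0.633 and chromosome 18 of 0.637. Relative to gene number, chromosome 17 had the lowest ratio of all, 0.288 (adjusted p = 1.3e-15, exact binomial test). Chromosome 3 lost its call relative to gene number (adjusted p = 0.102), and chromosomes 17 and 18 lost theirs among autosomes alone (adjusted p = 0.0523 and 0.0565, exact binomial tests). Chromosome 18 also lay above its expectation relative to gene number, at 1.25, without passing (adjusted p = 0.314, exact binomial test). The 11 chromosomes that did not pass the threshold had ratios between 0.766 and 1.23 by this span. Several of them passed under another expectation. Chromosome 21 passed at 2.97 without the longest peak-free stretches, where its span fell from 35.7 to 11.3 Mb. Chromosome 22 passed at 0.437 with the span counted from position 1, which adds its unassembled p arm. Relative to gene number, chromosome 22 passed at 0.304, chromosome 11 at 0.508, chromosome 1 at 0.750 and chromosome 8 at 1.50. Chromosome 12 passed with the span counted from position 1 (1.28) and among autosomes alone (1.29), and chromosomes 7 (0.761) and 11 (0.741) passed without chromosome 5. For chromosomes 21 and 22, with 22 and 11 peaks, the direction differed between these expectations.

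**Figure D1:**
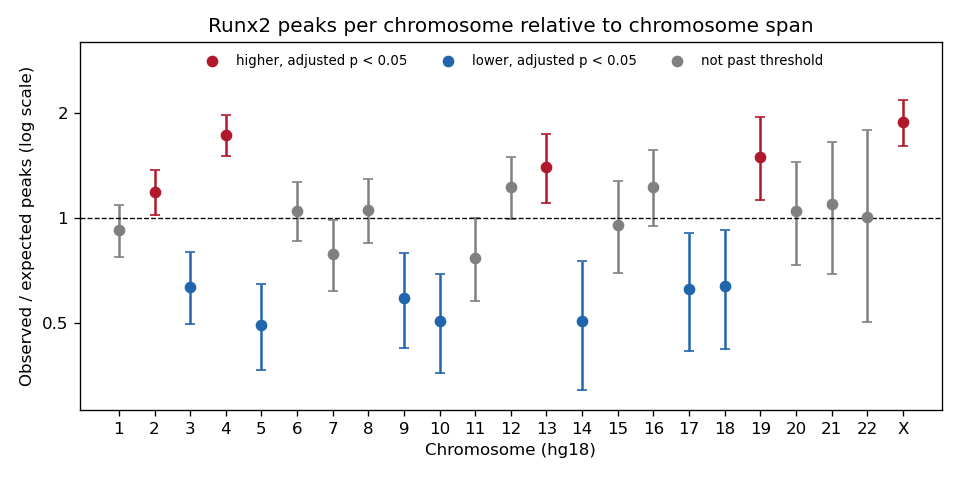
Observed over expected number of Runx2 peaks (log scale) for each autosome and X, with the expectation from the chromosome's share of the summed span. Points are ratios and bars exact 95% intervals, which cover counting error only; X at 1.89 and chromosome 4 at 1.73 lie highest, and chromosome 5 at 0.490 lowest by this span.

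The uneven spread over chromosomes was larger than in draws of independent peaks, with a chi-square of 255 (22 degrees of freedom, p = 1e-05, the smallest that the draws can give). Because peaks lay in groups, these draws overstate the evidence, as does the binomial test for single chromosomes. In the permutation of 10 Mb windows, which keeps the peaks of each window together, the unevenness also passed (permutation p = 8e-05). With 10 Mb windows as the units, 2 chromosomes passed the threshold in place of 12, X and 4, each with an adjusted p of 0.00437 in the permutation test. The ratios of the chromosomes that lost their call stayed similar, such as 0.517 for chromosome 5, 0.515 for chromosome 10 and 0.485 for chromosome 14. X averaged 9.94 ± 6.57 peaks per window (SD, n = 16 windows) and chromosome 4 averaged 9.25 ± 5.65 (SD, n = 20 windows), against 5.27 over all 304 windows. The counts varied more from window to window than independent peaks would, with a variance 4.29 times the mean. On X the highest window, from 40 to 50 Mb, held 28 peaks, and on chromosome 4 the first 10 Mb held 26. Without these single windows the ratios were 1.68 for X and 1.61 for chromosome 4 (adjusted p = 0.0419 and 0.0374, permutation test). When peaks chained within 1 Mb were counted once, 0 chromosomes passed the threshold of the exact binomial test, and 1 had an unadjusted p below 0.05. That count lowers the ratio of any dense chromosome, to 1.22 for evenly spread peaks at the density of X, where 1.28 was observed.

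**Figure D2:**
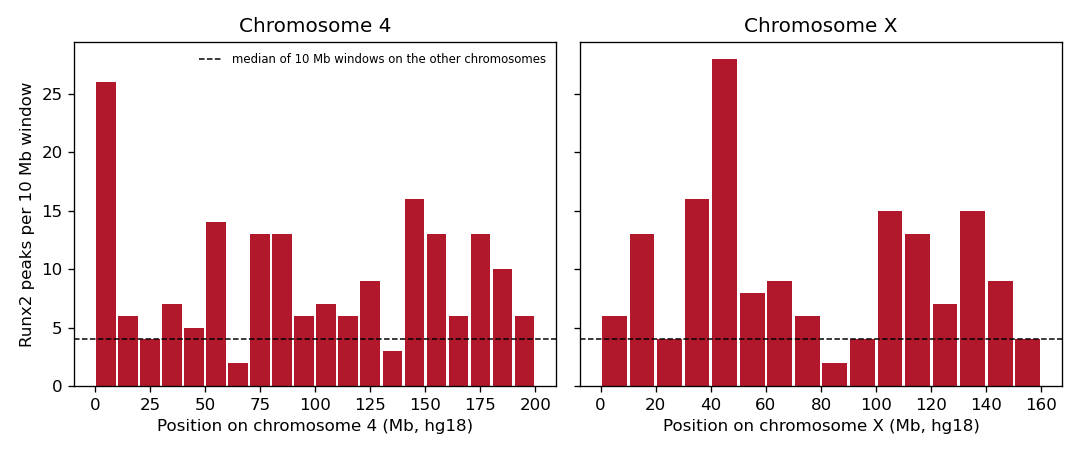
Runx2 peaks per 10 Mb window along chromosomes 4 and X (build hg18), with the dashed line at the median of 4 peaks over 268 windows of the other chromosomes. On X 12 of 16 windows and on chromosome 4 17 of 20 windows lie above that median.

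The second comparison asked whether Runx2 peaks lay closer together than scattered peaks would. Neighbouring peaks were closer than in random placements at every distance examined from 5 to 100 kb. The median gap was 606 kb, against 1109 kb in random placements (middle 95% 1050 to 1168 kb). Close pairs, with a gap of at most 10 kb, numbered 74, against 10.9 ± 3.27 in random placements (SD, n = 1000 placements), or 6.80 times as many (one-sided permutation p = 0.001, the smallest that the placements can give). Within 5 kb there were 41 pairs against 5.64 expected, and within 100 kb 310 pairs against 99.9 expected. Within 1 kb there were 3 pairs against 1.58 expected, which did not pass the test (one-sided permutation p = 0.215). Close pairs were found on 18 of the 23 chromosomes. X held the most, with 10 pairs, and without X the excess was 7.08 times.

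**Figure D3:**
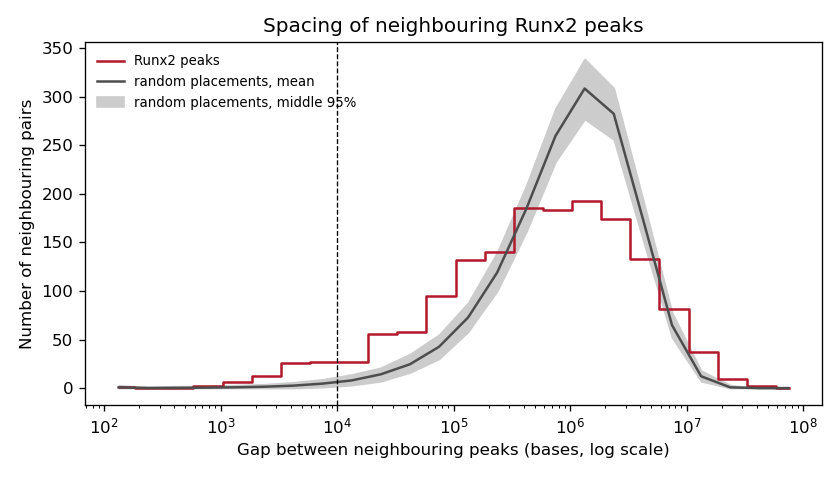
Number of neighbouring pairs of Runx2 peaks by the gap between them (bases, log scale; red steps), with the mean of 1000 random placements (line) and their middle 95% (grey band); the dashed line marks 10 kb. The peaks exceed the placements at gaps of up to 100 kb, where the excess within 1 kb did not pass the test, and fall short of them around 1 Mb.

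The close pairs joined 145 peaks, 9.05% of those on the autosomes and X, into 71 groups. Of these, 68 held 2 peaks and 3 held 3 peaks. The first group of 3 spanned 12.8 kb of chromosome 2, from 111209212 to 111222036. The next spanned 10.3 kb of chromosome 5, from 1000677 to 1010933, and the last spanned 7.57 kb of X, from 149208242 to 149215808. Chained within 100 kb, 544 peaks (34.0%) fell into 234 groups. The 2 largest held 5 peaks each. They lay on chromosome 5 from 909123 to 1010933, which contains the group of 3 named above, and on chromosome 10 from 134212704 to 134367045. These 2 were chosen after their values were seen, as were the windows that follow.

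At the scale of 1 Mb, the peaks occupied 937 windows, against 1191 in random placements (middle 95% 1166 to 1217, one-sided permutation p = 0.001, the smallest that the placements can give). The densest window was on X from 39 to 40 Mb, where 11 peaks lay between 39075231 and 39839709. The densest window of a random placement held 5.12 peaks on average and at most 10. Windows of 6 or more peaks numbered 15, against 0.248 per random placement. With placements kept outside the longest peak-free stretch, the 11 peaks were 2.02 times the average of the densest window (one-sided permutation p = 0.002). Windows of 8 peaks lay on chromosome 6 from 168 to 169 Mb, on chromosome 10 from 134 to 135 Mb and on chromosome 12 from 28 to 29 Mb. Windows of 7 peaks lay on chromosome 2 from 119 to 120 Mb and on chromosomes 4 and 8, both from 1 to 2 Mb.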

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

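The number of peaks, 1603, was also 1603 with overlapping peaks merged and 1600 with peaks within 1 kb merged. The excess of close pairs kept its direction and significance in 6 of 7 alternatives, at 2.91 to 7.27 times expectation, the lowest when each peak was moved within its own 1 Mb bin. Within 1 kb it did not pass, at 1.90 times (3 pairs, one-sided permutation p = 0.215). The unevenness over chromosomes passed the test in 8 of 9 alternatives, of which 3 were planned and 6, including those based on windows and on chained peaks, were chosen after seeing the data. It did not pass with peaks chained within 1 Mb counted once, where the chi-square was 27.7 (p = 0.185) and 0 chromosomes passed the adjusted threshold. There, 1 chromosome had an unadjusted p below 0.05, and the setting saturates on dense chromosomes, as the ratio of 1.22 for evenly spread peaks at the density of X shows. With 10 Mb windows as the units, 2 chromosomes passed in place of 12. Relative to gene number, ratios crossed 1 on chromosomes 18 (to 1.25, adjusted p = 0.314), 19 (to 0.447), 16 (to 0.891), 20 (to 0.813) and 22 (to 0.304), with 19 and 22 past the threshold of the exact binomial test; by construction that setting expects more peaks on gene-rich chromosomes. X and chromosome 4 stayed above their expectation and past the threshold in each alternative that included them, apart from the 1 Mb chaining. The planned stricter thresholds, the alternatives on score and width, on location and gene lists and on the motif were not run, since the scores do not vary and no hg18 genome or annotation was used here. No paired analysis was possible because each group has 1 library and only the Runx2 library was compared with chance. Depth is unknown, so how many further sites more reads would reveal cannot be judged.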

Other observations

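The tests in this part on chaining within 100 kb for X and chromosome 4, on windows along them and on pairs within 1 kb were chosen only after the values they bear on were seen. The expectation from gene number was planned, but its reading as a test of gene content was written after its value was seen, and the end regions were examined because dense windows near chromosome ends had been noticed.

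Runx2 peaks were dense near the ends of chromosomes. The first 5 Mb of the 18 chromosomes with an assembled p arm held 100 of the 1428 peaks on them, against 49.0 in random placements between position 1 and the last peak of each chromosome (2.04 times, one-sided permutation p = 0.001, the smallest that the placements can give). Chromosome 4 contributed 16 of these, chromosome 8 12, chromosome 5 11 and chromosome 2 10, while chromosomes 3 and 9 had 0. The number exceeded expectation on 11 of the 18 chromosomes (exact sign test p = 0.481), so it was not shown that the excess is general to chromosomes. The sign test takes the odds of lying above expectation as even, which need not hold for such small counts. Within 2 Mb of the start the ratio was 3.32 (65 peaks) and within 10 Mb it was 1.77. The other end was taken as the last peak of each chromosome. Its distance from the chromosome end was not measured, since chromosome lengths of build hg18 were not used here. Within 5 Mb of the last peak lay 180 peaks, against 62.7 in random placements between the first and last peak (2.87 times). Counting from a peak raises this ratio wherever peaks lie in groups. Set against rotated peak patterns, which are also counted from a peak, the number was higher on 21 of 23 chromosomes (exact sign test p = 6.6e-05).

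For the dense ends, 3 technical explanations were tested. Grouping of peaks wherever it falls was tested by rotating each chromosome's own peak pattern, which for the other end meant counting from a peak drawn at random. At the start the observed number, 100, was 2.01 times the mean of the rotations (one-sided permutation p = 0.002), whose highest was 109. At the other end the observed number, 180, was 1.80 times the mean (one-sided permutation p = 0.001), and the highest rotation held 155. Dense windows had been noticed at the ends before this test, so its p-values overstate the evidence and grouping is not excluded. Counting chained peaks within 100 kb once left 1.81 times at the start, and leaving out chromosome 4, which had the most, left 1.90 times, which argues against repeated counting and against a single chromosome as the whole cause. Gene density, base composition and the mapping of reads near chromosome ends were not tested, since they need a genome of build hg18, and they stay open.

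X and chromosome 4 carried more peaks than their span gives. Peak numbers in proportion to gene number alone do not account for the uneven spread as a whole, since that expectation raised the chi-square from 255 to 688. Gene content considered together with span was not tested. Local groups were tested by counting peaks within 100 kb of each other once, and the lower bounds of the ratios stayed at 1.43 for X and 1.44 for chromosome 4. Groups on a scale of 1 Mb cannot be told apart from even density by the chaining test, because the measure saturates; its lower bounds were 0.939 for X and 0.963 for chromosome 4. A factor that acts along the whole chromosome, such as copy number in C4-2B cells, also stays open: 75% of the 10 Mb windows on X and 85% on chromosome 4 lay above the median of the other chromosomes, but both chromosomes were picked for their high counts, which raises these shares, and copy number was not measured. A biological preference along these chromosomes was not tested.

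The close spacing of peaks was set against 2 technical explanations. Regional density at the 1 Mb scale does not account for all of it. The 74 close pairs were 2.91 times the 25.4 found on average when each peak was moved within its own 1 Mb bin. That average was itself above the 10.9 of placements over the span. Density at scales between 10 kb and 1 Mb was not tested. A single binding site reported as several peaks was examined by the share of close pairs within 1 kb. That share was 4.05% (3 of 74, exact 95% interval 0.844% to 11.4%). It cannot exclude split sites, because the peak caller and any merging or spacing of near calls are unknown. Broad sites split at more than 1 kb would also be missed, and 41 pairs lay within 5 kb. The hypothesis that neighbouring Runx2 peaks mark separate elements of one locus stays untested, because genes, motifs and peak heights were not analysed here. The closest pair, 117 bases apart, lay on chromosome 3 at 197035348 to 197035847 and 197035965 to 197036464.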
